A study of Mus musculus with 8 samples.

How the data were processed

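Gene expression was measured in 8 mouse colonic tumor samples on Affymetrix MoGene 1.0 ST arrays, with 1 array per sample. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit and labelled with biotin. The deposited values are log2 signals from robust multi-array average (RMA), per the submitters' processing notes, which name GCOS and RMA. The versions of both, the chip annotation and the RMA settings were not given in the sources used here. The table held 35557 probe sets, and its values ran from 0.564 to 13.5 with array medians over genes between 4.17 and 4.31, which fits a log2 scale. No further transformation, scaling or background subtraction was applied before testing.

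A probe annotation table listed genes for 23410 of the probe sets, of which 21789 carried exactly 1 gene symbol and 1621 carried several. The 12147 probe sets without a listed gene and those with several symbols were not tested. Of the probe sets with 1 symbol, 21698 matched a symbol of the mouse RefSeq table, and 0 symbols were changed. For the 999 genes with more than 1 probe set, the probe set with the highest mean over all 8 arrays was taken, which left 19938 genes. No filter on dim genes was applied.

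The samples fell into 3 groups by genotype label: 3 azoxymethane (AOM) tumors labelled K-rasG12Dint, 2 AOM tumors labelled LSL-K-rasG12D/+ and 3 serrated tumors labelled K-rasG12Dint with Ink4a/Arf-/-. No array was left out. The 4 contrasts were taken from 1 limma fit of the 3 group means to all 8 arrays, with 5 residual degrees of freedom and with the trend and robust options off. Each gene thus had 1 spread shared by the 3 groups. Where a gene varied more between serrated than between AOM arrays, errors and p-values of contrasts with the serrated group are too small. For such a gene those between the AOM groups are too large. The serrated group was set against the mean of both AOM group means, against each AOM group alone, and the AOM groups were set against each other. P-values were adjusted by the Benjamini-Hochberg method over all genes of a contrast, and an adjusted p under 0.05 was taken as passing. All p-values on genes in the text come from limma. An error beside a log2 difference is its standard error (SE), and an error beside a level is a standard deviation (SD). For arrays, only their number limits the precision that can be stated. Each sample title carries a different number, but the labels do not say whether it stands for an animal. Whether samples of a group came from separate animals is therefore not known. The p-values measure the spread between these samples, which is possibly technical in part.

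Gene lists for pathways, epithelial lineages and other cell types, 34 in all, were fixed with their members before the data were examined, as were the contrasts, the test, the alternatives below and the rule for named genes. The lists held 497 genes in 509 entries, of which 461 genes and 473 entries were measured, 2 of them through a synonym. Lists were tested with camera in limma with a preset correlation of 0.01, adjusted over the 34 lists of a contrast, with an adjusted p under 0.05 as passing. Camera with an estimated correlation and fry were run beside it. Fry asks whether the genes of a list move on balance 1 way and does not compare the list with other genes. Members of each list were counted past the threshold over all genes and when adjusted over the list alone. The lists described for the contrasts of the serrated group with each single AOM group, and those described at length between the AOM groups, were chosen after their values were seen.

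The rule for named genes always took Cdkn2a, Ctnnb1, Apc and Vil1, and the other genes it always took were not analysed here. For serrated tumors against all AOM tumors and for the AOM groups against each other it added the 10 genes with the largest rise and the 10 with the largest fall past the threshold, provided the arrays of the groups did not overlap. The other contrasts took 5 each way. Where fewer passed, the genes of smallest p were taken up to 5 each way and are said not to pass. From each list described, up to 4 members with the smallest adjusted p were named. Predicted genes without a name were to be skipped, and 0 were met. Genes named beyond this rule are said to be chosen after their values were seen.

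The fit was tested on simulated data for the 19938 genes in 20 runs with 200 changed genes each. It recovered 46.0% of 2-fold and 88.2% of 4-fold changes for serrated against all AOM tumors, and 33.5% and 84.5% for serrated against K-rasG12D AOM tumors. It recovered 25.5% and 78.3% for the AOM groups against each other, and 22.1% and 79.4% for serrated against LSL AOM tumors. Genes that had not been changed made up 4.52%, 5.07%, 4.64% and 4.25% of the calls in these contrasts, in the same order. A list shifted on purpose was called in 20 of 20 runs with either correlation. Lists that share no gene with it were called 5 times over all runs. The simulated noise was independent between genes, and each gene had the same SD in every group. The simulation therefore held no correlation between genes and no array more variable than the others. It does not check the list calls or the shares of false calls where these are present.

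The alternatives were the mean of all probe sets of a gene, every probe set tested on its own, the dimmest 40% of genes left out, the trend or the robust option in limma, and quantile normalization or median centring of the deposited values. Array weights, a fit to only the groups compared and each array left out in turn were also run. Array weights by the gene-by-gene method were added after the data were seen. No scan date or batch was given in the sources used here, so no batch term was fitted. The work used R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.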

Results

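Transcript levels were compared between chemically induced and serrated colonic tumors of mice labelled as K-rasG12Dint, here called K-rasG12D, or LSL-K-rasG12D/+, here called LSL. AOM is azoxymethane, a colon carcinogen. LSL stands for lox-stop-lox, a cassette that keeps an allele silent until a recombinase removes it. The K-rasG12D AOM group (3 arrays) and the LSL AOM group (2 arrays) were tumors of the distal colon. The serrated group (3 arrays) was made of tumors of the proximal colon with K-rasG12D and without Ink4a/Arf, the locus of the Cdkn2a cell-cycle inhibitors. The sample titles name AOM for both AOM groups and not for the serrated group. Tumor type, AOM, colon segment and Ink4a/Arf genotype therefore went together in every comparison with the serrated group and could not be separated. The first 2 principal components held 48.7% and 21.3% of the variance. Serrated replicates 1 and 3 lay at opposite ends of the second component, at 49.4 and -52.3. Serrated replicate 1 also had an SD over genes of 1.77, against 2.00 to 2.13 on the other 7 arrays.

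Cdkn2a, the gene targeted in the serrated group, was measured first. Its level was 5.39, 6.21 and 5.95 in the K-rasG12D AOM tumors, 3.59 and 4.28 in the LSL AOM tumors, and 4.01, 3.79 and 3.37 in the serrated tumors. The group means were 5.85 ± 0.42 (SD, n = 3), 3.93 ± 0.49 (SD, n = 2) and 3.72 ± 0.33 (SD, n = 3). Serrated and LSL AOM arrays overlapped in this gene. Whether its probe set lies in the deleted part of the locus is not known, so these levels do not check the genotype labels.

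The series title sets AOM-induced tumors against serrated tumors, and the first comparison asked how their transcripts differ. All samples were tumors, and no normal colon was measured. Rose and fell therefore mean higher or lower in serrated tumors than in the AOM tumors set against them. Which of the groups departs from normal colon is not known. In serrated tumors 8 of 15 stomach genes and 7 of 18 small-intestinal enterocyte genes rose, and 18 of 20 Wnt targets, 5 of 14 posterior Hox and distal colon genes and 5 of 15 protease and invasion genes fell. All 5 lists were called with the preset correlation, and with an estimated correlation only the Wnt list was (adjusted p = 0.0248, against 0.0979 to 0.339 for the others). Gkn1, a secreted protein of stomach surface cells, stood at 10.44 ± 1.73 (SD, n = 3) in serrated and 3.95 ± 0.20 (SD, n = 5) in AOM tumors, and its log2 difference of 6.50 was 7.48 without serrated replicate 1. Wif1, a secreted Wnt inhibitor, stood at 3.95 ± 0.43 (SD, n = 3) and 9.21 ± 0.24 (SD, n = 5), with a log2 difference of -5.27. Levels near 4 lie below the median gene of every array, so folds against them are uncertain.

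Stomach genes made up much of the largest rises in serrated tumors. Of the 15 measured gastric epithelium genes, 8 rose, 0 fell and 7 did not pass, while 13 passed when adjusted over the list alone. The list had a median log2 difference of 3.73 and an adjusted p of 1.40e-09 in camera, and adjusted p = 0.339 with an estimated correlation. Gkn2 rose by 7.06 ± 0.68 on the log2 scale (adjusted p = 0.000889), and Gkn1 by 6.50 ± 0.62 (0.000872). The trefoil peptides Tff1 and Tff2 rose by 6.14 ± 0.62 (adjusted p = 0.00103) and 6.16 ± 0.97 (0.00681). Muc5ac, the main mucin of the stomach surface, rose by 6.32 ± 0.87 (adjusted p = 0.00395), and the mucin-like gene Mucl3 by 6.41 ± 0.81 (0.00261). On serrated replicate 1, Muc5ac and Tff2 stood at 6.28 and 6.17, against 10.7 and 10.9 on replicate 2 and 10.4 and 10.9 on replicate 3. On the AOM arrays Muc5ac ran from 2.64 to 2.97 and Tff2 from 2.93 to 3.42. The fit shares 1 spread over all groups, so errors and p-values of stomach genes that vary like this are too small.

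Among genes of intestinal absorption, 7 of 18 measured small-intestinal enterocyte genes rose, 0 fell and 11 did not pass. Adjusted over the list alone, 11 rose. The median was 1.28 and the camera adjusted p was 9.75e-09, with adjusted p = 0.0979 for an estimated correlation. Leaving out the dimmest 40% of genes raised the median to 2.33. Fabp2, which binds fatty acids, rose by 5.96 ± 0.32 (adjusted p = 5.21e-05). Its level was 8.84 ± 0.72 (SD, n = 3) in serrated tumors and 2.78 ± 0.61 (SD, n = 5) over the AOM arrays, whose mean weights the AOM groups by their arrays, whereas the difference weights them equally. Rbp2, which binds retinol, rose by 4.83 ± 0.33 (adjusted p = 0.000189). Intestinal alkaline phosphatase Alpi rose by 4.14 ± 0.27 (0.000134), and Apob, a protein of chylomicrons, by 4.14 ± 0.35 (0.000537).

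Of 18 absorptive colonocyte genes, 10 rose, 0 fell and 8 did not pass, with 14 adjusted over the list alone. The median was 1.3 and the camera adjusted p 2.06e-08, with adjusted p = 0.0979 for an estimated correlation. Cdhr5, a brush border cadherin, rose by 1.60 ± 0.17 (adjusted p = 0.00120), and Mep1a, a brush border protease, by 4.02 ± 0.45 (0.00143). The chloride exchanger Slc26a3 rose by 4.64 ± 0.88 (0.0145) and the adhesion protein Ceacam1 by 0.93 ± 0.18 (0.0148). Without serrated replicate 2 or LSL replicate 2 neither Slc26a3 nor Ceacam1 passed, and without LSL replicate 1 Slc26a3 did not (adjusted p between 0.0504 and 0.0739).

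Goblet cell genes also rose, 5 of 13 measured, with 0 falling, 8 not passing and 6 adjusted over the list alone. The median was 0.84 and the camera adjusted p 0.000230, with adjusted p = 0.339 for an estimated correlation, and array weights lowered the median to 0.46. Sytl2, a vesicle protein, rose by 2.01 ± 0.27 (adjusted p = 0.00342), and Clca1, a secreted mucus protein, by 3.71 ± 0.61 (0.00823). Spdef, a transcription factor of goblet cells, rose by 1.01 ± 0.18 (0.0126), and Creb3l1 by 0.84 ± 0.17 (0.0190). St6galnac1, chosen after its values were seen, rose by 1.02 ± 0.27 (0.0468). Creb3l1 did not pass without serrated replicate 2 or LSL replicate 1 (adjusted p of 0.0755 to 0.0786), and St6galnac1 passed only in the full set and without serrated replicate 2 (otherwise 0.0685 to 0.137).

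Of 14 enteroendocrine genes, Nts (1.12 ± 0.24, adjusted p = 0.0223) and Sst (1.19 ± 0.29, 0.0360), both peptide hormones, rose, 0 fell and 12 did not pass. Adjusted over the list alone, 3 rose and 1 fell. Of 8 adipocyte genes, the lipid droplet gene Cidec (2.10 ± 0.23, 0.00135) and the nuclear receptor Pparg (1.71 ± 0.28, 0.00796) rose, 0 fell and 6 did not pass, with 3 adjusted over the list alone. Both genes are also expressed outside fat. The camera adjusted p values were 0.0441 and 0.0261, with adjusted p = 0.591 and 0.261 for an estimated correlation. The enteroendocrine list was not called without serrated replicate 1 (adjusted p = 0.271), K-rasG12D replicate 2 (0.0919) or LSL replicate 2 (0.0796), and adipocyte genes were not without serrated replicate 1 (0.0827). Nts did not pass without K-rasG12D replicate 1, serrated replicate 2 or either LSL array (0.0558 to 0.0998), nor Sst without any array but serrated replicate 3 (0.0567 to 0.154).

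The other largest rises were those of enzymes. The cytochromes Cyp2c55 and Cyp2c65 rose by 6.10 ± 0.96 (adjusted p = 0.00663) and 4.96 ± 0.97 (0.0163), and the phospholipase Pla2g4c by 5.14 ± 0.90 (0.0102). Cyp2c65 did not pass without serrated replicate 2 or LSL replicate 2 (adjusted p of 0.0637 to 0.0811). Signals of the Cyp2c genes, which have near-identical copies, are uncertain as to the copy.

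Wnt target genes fell in serrated tumors: 18 of the 20 measured passed, all lower, 2 did not, and all 20 passed when adjusted over the list alone. The median was -2.75, the camera adjusted p was 1.71e-28, and adjusted p = 0.0248 with an estimated correlation. Of the 17 lists called in this comparison, it was the only 1 that also passed with an estimated correlation. Wif1 fell by 5.27 ± 0.23, the Wnt feedback inhibitor Nkd1 by 4.23 ± 0.19 and the transcription factor Prox1 by 4.73 ± 0.22 (adjusted p = 3.15e-05 for each). Sox4, also a transcription factor, fell by 3.33 ± 0.18 (5.21e-05). Ctnnb1, the gene of beta-catenin, differed by -0.53 ± 0.15 (adjusted p = 0.0635), and Apc, its negative regulator, by 0.76 ± 0.21 (0.0531). Neither passed, nor did Vil1, an epithelial brush border protein, at 0.60 ± 0.19 (0.0901).

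Of 12 crypt stem cell genes, 8 fell, 1 rose and 3 did not pass, with 9 and 1 adjusted over the list alone. Of its genes, 4 are also in the Wnt list. The median was -1.40 and the camera adjusted p 5.92e-06, with adjusted p = 0.116 for an estimated correlation. Axin2, a Wnt feedback gene, fell by 3.79 ± 0.23 (adjusted p = 0.000102), and Ascl2, a stem cell transcription factor, by 2.35 ± 0.19 (0.000446). Lgr5, the receptor that marks crypt stem cells, fell by 3.10 ± 0.46 (0.00534), and Tnfrsf19 by 1.55 ± 0.18 (0.00170). Olfm4, a secreted glycoprotein chosen after its values were seen, rose by 4.29 ± 0.90 (0.0219). Its call was lost without K-rasG12D replicate 2, serrated replicate 2 or either LSL array (adjusted p of 0.0537 to 0.0998).

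Cell cycle genes fell as a group, 9 of 21 measured, with 0 rising, 12 not passing and 15 adjusted over the list alone. The median was -0.89 and the camera adjusted p 1.50e-08, with adjusted p = 0.440 for an estimated correlation. The mean level of the list was 5.39 and 5.53 on serrated replicates 1 and 2 but 6.44 on replicate 3, within the 6.38 to 6.52 of the K-rasG12D AOM arrays and below the LSL arrays at 6.81 and 6.75. The mitotic kinase Plk1 fell by 1.07 ± 0.20 (adjusted p = 0.0144), and the replication genes Mcm2, Pcna and Top2a by 1.53 ± 0.32 (0.0210), 1.14 ± 0.25 (0.0241) and 1.31 ± 0.29 (0.0255). None of these 4 passed without serrated replicate 2 or LSL replicate 1, nor all but Plk1 without LSL replicate 2, nor Pcna and Top2a without K-rasG12D replicate 2, nor Top2a without K-rasG12D replicate 1 (adjusted p of 0.0504 to 0.116).

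Of the 14 posterior Hox and distal colon genes, 5 fell, 0 rose and 9 did not pass, with 5 adjusted over the list alone. The median was -0.33 and the camera adjusted p 0.00830, with adjusted p = 0.261 for an estimated correlation. Hoxd13, the last gene of its cluster, fell by 4.85 ± 0.34 (adjusted p = 0.000206), from 7.79 ± 0.61 (SD, n = 5) to 2.94 ± 0.26 (SD, n = 3). Hoxb13 fell by 3.17 ± 0.28 (0.000579), Hoxd11 by 1.75 ± 0.22 (0.00259) and Hoxd10 by 1.68 ± 0.31 (0.0128), as did Hoxb9, chosen after its values were seen, by 1.01 (0.0144). The median was -0.51 without serrated replicate 1 and -0.17 without serrated replicate 2. Hoxd10 did not pass without serrated replicate 2 or LSL replicate 1, nor Hoxb9 without serrated replicate 2 or LSL replicate 2 (adjusted p of 0.0506 to 0.0774).

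Matrix protease genes and macrophage genes fell. Of 15 protease and invasion genes, 5 fell, 0 rose and 10 did not pass, with 11 adjusted over the list alone. The median was -1.47 and the camera adjusted p 1.98e-07, with adjusted p = 0.330 for an estimated correlation. The proteases Mmp7, Mmp14 and Mmp9 fell by 4.38 ± 0.27 (adjusted p = 0.000102), 2.44 ± 0.27 (0.00133) and 2.17 ± 0.32 (0.00539). Mmp7 is also in the Wnt and Paneth cell lists, and Mmp9 in the neutrophil list, so their falls are not separate support for this list. Timp1, a protease inhibitor, fell by 1.47 ± 0.20 (0.00355), and Mmp2, chosen after its values were seen, by 1.5 (0.0252). The mean level of the list was 4.40 and 4.32 on serrated replicates 1 and 2 but 5.69 on replicate 3, against 6.13 to 6.64 on the AOM arrays. Of 14 macrophage and dendritic cell genes, 6 fell, 0 rose and 8 did not pass, with 11 adjusted over the list alone. That list had a median of -0.92 and a camera adjusted p of 4.10e-06, with adjusted p = 0.330 for an estimated correlation. Lysozyme Lyz2, which has a near-identical copy, fell by 2.67 ± 0.45 (0.00908), the complement genes C1qa and C1qb by 1.21 ± 0.21 (0.0103) and 1.17 ± 0.23 (0.0168), and the lysosomal Cd68 by 1.27 ± 0.29 (0.0291). C1qa, C1qb, Cd68 and Mmp2 did not pass without serrated replicate 2, nor C1qb, Cd68 and Mmp2 without LSL replicate 1, nor Cd68 and Mmp2 without serrated replicate 1 or K-rasG12D replicate 2 or 3, nor Cd68 without LSL replicate 2 (adjusted p of 0.0522 to 0.116).

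Of 14 fibroblast genes, the collagens Col1a1 (-1.47 ± 0.29, adjusted p = 0.0161), Col3a1 (-1.42, 0.0247) and Col1a2 (-1.41, 0.0273) fell, 0 rose and 11 did not pass, with 6 adjusted over the list alone. Of 13 mesenchymal and EMT (epithelial-mesenchymal transition) genes, the filament Vim (-1.75 ± 0.27, 0.00561), the matrix protein Fn1 (-1.92 ± 0.30, 0.00631) and Tgfbi (-1.17, 0.0304) fell, 0 rose and 10 did not pass, with 5 adjusted over the list alone. Fibroblasts and macrophages also express these 3 genes. On serrated replicate 3 the mean levels of the fibroblast and mesenchymal lists, 6.0 and 5.12, lay above those of LSL replicate 2, 5.95 and 5.07. Smooth muscle genes (median 0.46, adjusted p = 0.412) and endothelial genes (median -0.15, 0.480) were not called. Of 12 smooth muscle genes, 1 passed, the actin-binding Cald1, which fell by 0.94 (adjusted p = 0.0244) and did not pass without K-rasG12D replicate 1 or 2, serrated replicate 2 or LSL replicate 1 (0.0591 to 0.104). The camera adjusted p was 0.00424 for fibroblast and 0.00830 for mesenchymal genes, with adjusted p = 0.441 for an estimated correlation in both lists. The mesenchymal list was not called when the dimmest 40% of genes were left out (adjusted p = 0.0654), and its median moved from -0.29 to -0.65 without serrated replicate 3, while that of fibroblast genes moved from -0.92 to -0.60 without LSL replicate 1. Col1a1, Col3a1, Col1a2 and Tgfbi did not pass without serrated replicate 2, nor the last 3 without K-rasG12D replicate 2 or LSL replicate 1, nor Col1a2 and Tgfbi without serrated replicate 1 or K-rasG12D replicate 3, nor Tgfbi without K-rasG12D replicate 1 (adjusted p of 0.0506 to 0.127).

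Of 17 senescence-associated secretory genes, the decoy receptor Tnfrsf11b (-3.94 ± 0.21, adjusted p = 5.21e-05), the chemokine Cxcl2 (-1.69 ± 0.30, 0.0118) and Igfbp7 (-1.17 ± 0.27, 0.0310) fell, 0 rose and 14 did not pass. Adjusted over the list alone, 7 fell. Of its genes, 4 are also in the protease list. The median was -0.83 and the camera adjusted p 0.000121, with adjusted p = 0.339 for an estimated correlation, and the median was -1.35 without serrated replicate 3. The mean level of the list on that array, 5.47, lay above that of LSL replicate 1, 5.34. Of 12 neutrophil genes, 1 fell, Mmp9, 0 rose and 11 did not pass, with 1 adjusted over the list alone. The neutrophil list had a camera adjusted p of 0.0391 and adjusted p = 0.577 for an estimated correlation. It was not called without K-rasG12D replicate 2 (adjusted p = 0.0681) or 3 (0.0597), serrated replicate 3 (0.166) or LSL replicate 2 (0.0847). Cxcl2 did not pass without serrated replicate 2, and Igfbp7 passed only in the full set and without K-rasG12D replicate 1 or serrated replicate 3 (otherwise 0.0527 to 0.135).

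Of 16 p53 target genes, 5 fell, 1 rose and 10 did not pass, with 6 and 1 adjusted over the list alone. The median was -0.36 and the camera adjusted p 0.0280, with adjusted p = 0.530 for an estimated correlation. Phlda3, an inhibitor of AKT, fell by 1.77 ± 0.23 (adjusted p = 0.00264) and Trp53inp1 by 1.44 ± 0.25 (0.00936). The kinase Plk2 fell by 2.12 ± 0.42 (0.0178) and the receptor Eda2r by 2.04 ± 0.42 (0.0196). Zmat3 (-0.87, 0.0469) and the adhesion gene Perp (0.64, 0.0341), chosen after their values were seen, also passed. The list was not called without serrated replicate 1 (median -0.12, adjusted p = 0.158), after quantile normalization (0.0894), with array weights (0.170) or without the dimmest 40% of genes (0.112). Plk2 and Eda2r did not pass without serrated replicate 2 or LSL replicate 1, nor Eda2r without LSL replicate 2. Zmat3 passed only in the full set and without K-rasG12D replicate 3 or serrated replicate 3, and Perp only in the full set and without serrated replicate 1 or 3 (all these adjusted p between 0.0637 and 0.161).

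The other largest falls were those of Spock2, a matrix proteoglycan, by 5.13 ± 0.26 (adjusted p = 4.59e-05), and of the retinol receptor Stra6 by 4.53 ± 0.20 (3.15e-05). The secreted phospholipase Pla2g2a fell by 5.01 ± 0.82 (0.00794), the acyl-CoA synthetase Acss3 by 4.50 ± 0.51 (0.00163), and Lcn2, an iron-scavenging protein, by 4.23 ± 0.45 (0.00127). Cdkn2a fell by 1.17 ± 0.25 (0.0247), although its arrays overlapped. Cdkn2a did not pass without K-rasG12D replicate 2 (adjusted p = 0.0568) or 3 (0.0537), serrated replicate 2 (0.0894) or LSL replicate 2 (0.0850).

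Lists for RAS/MAPK output and for glycolysis and hypoxia were not called as groups but held genes that passed. Of 19 RAS/MAPK genes, 3 fell, 1 rose and 15 did not pass, with a median of -0.12 and a camera adjusted p of 0.321. The transcription factor Etv5 fell by 2.25 ± 0.30 (adjusted p = 0.00346), Ier3 by 2.04 ± 0.31 (0.00542) and the MAP kinase phosphatase Dusp4 by 1.61 ± 0.27 (0.00812), and the membrane protein Emp1 rose by 2.19 ± 0.20 (0.000677). Of 16 glycolysis and hypoxia genes, 4 rose, 1 fell and 11 did not pass, with a median of 0.29 and a camera adjusted p of 0.0605. Carbonic anhydrase Car9 rose by 1.51 ± 0.22 (0.00498), Ndrg1 by 1.49 ± 0.23 (0.00623) and the glucose transporter Slc2a1 by 0.90 ± 0.15 (0.00812), and the enzyme Pgam1 fell by 0.96 (0.0141). Pgam1 did not pass without serrated replicate 2 or LSL replicate 2 (adjusted p of 0.0552 to 0.0559).

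In this comparison 1871 of 19938 genes passed in limma, 722 higher and 1149 lower in serrated tumors, and 1098 of them differed by 2-fold or more. At an unadjusted p under 0.05 there were 4933 genes. Of the 34 lists, 17 were called, 6 higher and 11 lower, and 13 passed in fry. The 17 other lists had adjusted p values from 0.0605 to 0.854. Without serrated replicate 1, 2090 genes passed and 58.1% of them were higher, against 38.6% of all called. Leaving out K-rasG12D replicates 1 and 2, serrated replicates 2 and 3 and LSL replicates 1 and 2 in turn gave 1037, 1014, 643, 3874, 797 and 895 genes, and array weights gave 10334. Median centring gave 1569 genes, of which 48.9% were higher. In a 2-group fit of 3 against 5 arrays, Cdkn2a (adjusted p = 0.162), Cxcl2, St6galnac1, Hoxb9, Perp and Zmat3 (0.0549 to 0.0718) did not pass. Other settings that ended calls of genes named here were quantile normalization for Nts (0.0692) and St6galnac1 (0.0702), array weights for St6galnac1 (0.0633), median centring and the trend option for Zmat3 and, for Top2a, a second, dim probe set (0.584). The enteroendocrine, neutrophil and adipocyte lists were not called with array weights (0.269, 0.179 and 0.126), nor the first 2 without the dimmest 40% of genes (0.0936 and 0.112), nor enteroendocrine genes after quantile normalization (0.149) or median centring (0.0515).

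**Figure D1:**
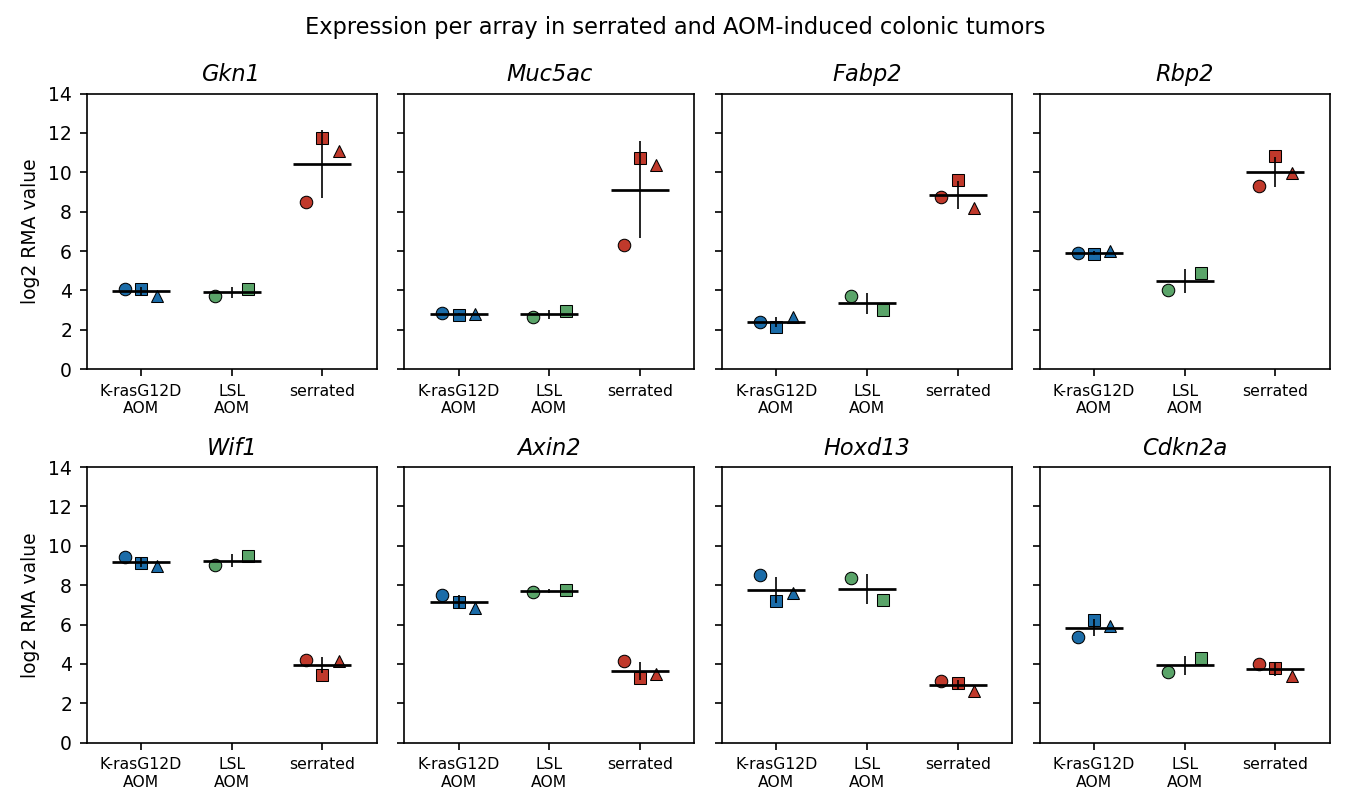
Log2 RMA values of 8 named genes on each of the 8 arrays, by group, with marker shape for the replicate, a line for the group mean and a bar for the SD. Gkn1, Muc5ac, Fabp2 and Rbp2 sit higher on every serrated array than on any AOM array, and Wif1, Axin2 and Hoxd13 lower, while Cdkn2a overlaps between the serrated and LSL AOM groups.

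**Figure D2:**
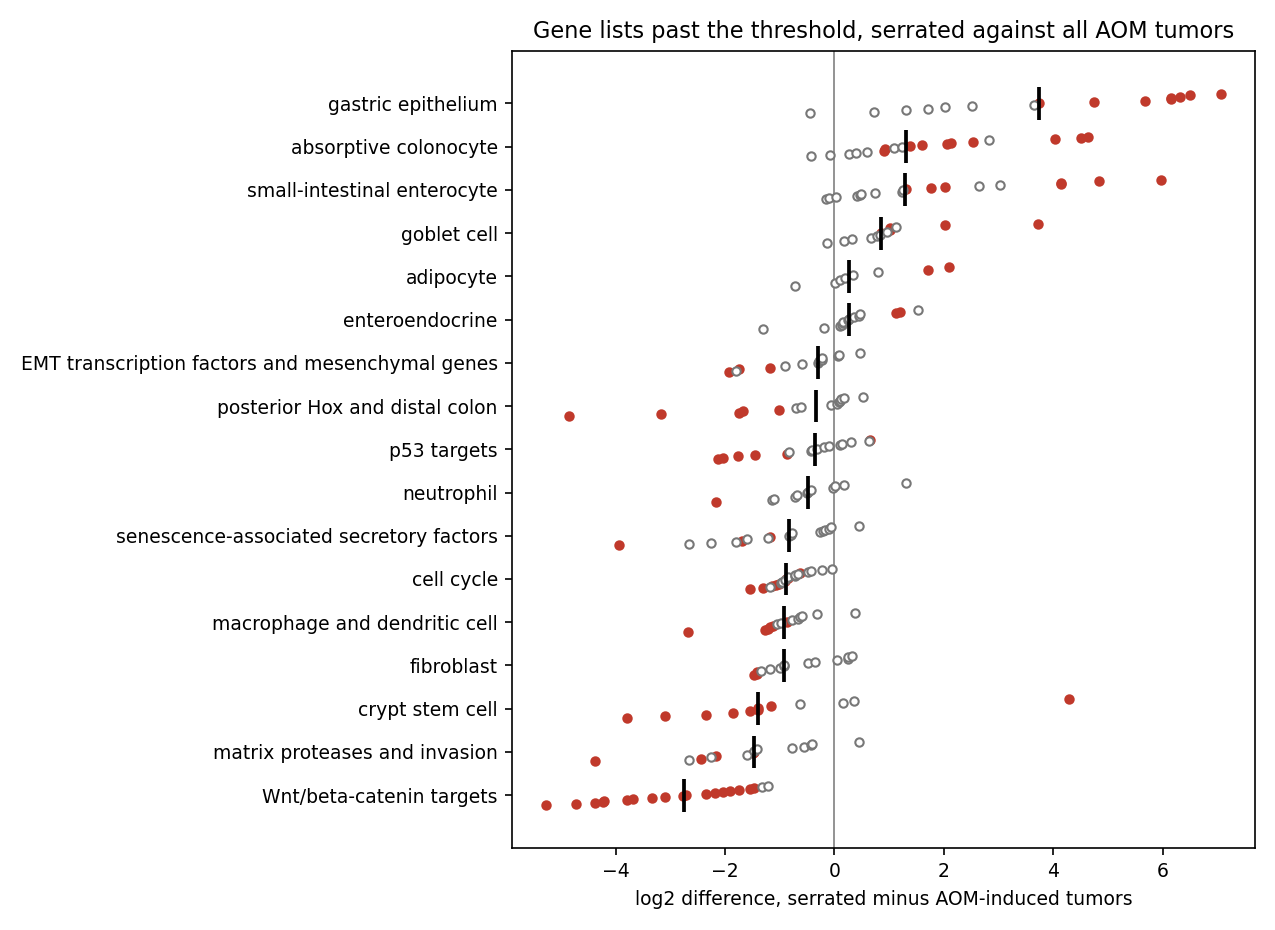
Log2 differences of the measured members of the 17 lists called for serrated tumors against all AOM tumors, where each point is a gene, filled points passed the threshold over all genes and the vertical bar is the list's median. All 20 measured Wnt targets lie below 0, with a median of -2.75.

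The next comparison set serrated tumors against the K-rasG12D AOM tumors. These groups share the K-ras label but differ in tumor type, AOM, colon segment and Ink4a/Arf genotype. In serrated tumors 6 of 15 stomach genes and 7 of 18 small-intestinal genes rose, and 18 of 20 Wnt targets, 5 of 15 protease and 5 of 17 senescence-associated secretory genes fell. With an estimated correlation only the Wnt list was called (adjusted p = 0.0241, against 0.0848 to 0.353 for the others). Gkn2 rose by 7.33 ± 0.76 on the log2 scale (adjusted p = 0.00186), and by 8.39 without serrated replicate 1, Cyp2c55 by 6.80 ± 1.06 (0.00892), Gkn1 by 6.47 ± 0.69 (0.00203), Fabp2 by 6.44 ± 0.36 (0.000146) and Mucl3 by 6.36 ± 0.90 (0.00581). Wif1 fell by 5.23 ± 0.25 (8.17e-05), Pla2g2a by 5.17 ± 0.91 (0.0144), Hoxd13 by 4.82 ± 0.38 (0.000576), Stra6 by 4.68 ± 0.22 (8.17e-05) and Acss3 by 4.49 ± 0.57 (0.00380). Cdkn2a fell by 2.13 ± 0.28 (0.00467), with all 3 serrated arrays below all 3 K-rasG12D arrays. Ctnnb1 (-0.23, adjusted p = 0.471), Apc (0.35, 0.423) and Vil1 (0.76, 0.0731) did not pass. Pla2g2a did not pass without K-rasG12D replicate 2 (adjusted p = 0.0683).

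Of the 20 Wnt targets, 18 fell, 0 rose and 2 did not pass, and 20 fell when adjusted over the list alone (median -2.59, camera adjusted p = 7.59e-29, and adjusted p = 0.0241 with an estimated correlation). Besides Wif1, the largest support came from Nkd1 (-3.64 ± 0.22, adjusted p = 0.000195), Prox1 (-4.05 ± 0.25, 0.000197) and Dkk2 (-4.24 ± 0.28, 0.000306), a further secreted Wnt regulator. Of 15 gastric genes, 6 rose, 0 fell and 9 did not pass, with 12 rising and 1 falling when adjusted over the list alone (median 3.59, camera adjusted p = 1.21e-08, and adjusted p = 0.353 with an estimated correlation). Tff1 rose by 6.23 ± 0.69 (0.00221) and Muc5ac by 6.32 ± 0.97 (0.00843), beside Gkn1 and Gkn2. Of 18 small-intestinal genes, 7 rose, 0 fell and 11 did not pass, with 9 adjusted over the list alone (median 1.31, camera adjusted p = 2.58e-09, and adjusted p = 0.0848 with an estimated correlation). They included Alpi (4.45 ± 0.30, 0.000306), Rbp2 (4.11 ± 0.37, 0.00101) and Apob (3.92 ± 0.39, 0.00152). Array weights moved the gastric median to 5.4, and leaving out the dimmest 40% of genes moved the small-intestinal median to 2.34.

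Of 15 protease and invasion genes, 5 fell, 0 rose and 10 did not pass, with 12 adjusted over the list alone (median -1.56, camera adjusted p = 1.21e-08, and adjusted p = 0.260 with an estimated correlation). Mmp7 fell by 4.36 ± 0.30 (adjusted p = 0.000314), Mmp14 by 2.68 ± 0.30 (0.00221), Timp1 by 1.8 ± 0.22 (0.00339) and Mmp9 by 1.56 ± 0.36 (0.0382). Of 17 senescence-associated secretory genes, 5 fell, 0 rose and 12 did not pass, with 6 adjusted over the list alone (median -1.33, camera adjusted p = 7.98e-06, and adjusted p = 0.260 with an estimated correlation). Tnfrsf11b fell by 4.12 ± 0.23 (0.000146) and the chemokines Cxcl2 and Cxcl1 by 2.57 ± 0.34 (0.00456) and 1.26 ± 0.26 (0.0263). Of 14 macrophage genes, 6 fell, 0 rose and 8 did not pass, with 11 adjusted over the list alone (median -1.12, camera adjusted p = 1.83e-06, and adjusted p = 0.260 with an estimated correlation). Mmp9 and Cxcl1 did not pass without serrated replicate 2 or any of the K-rasG12D arrays, nor Mmp9 without serrated replicate 1 (adjusted p of 0.0662 to 0.145) or after median centring.

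Genes driven by RAS/MAPK signalling fell as a group in camera: of 19 measured, 4 fell, 1 rose and 14 did not pass, with 7 and 2 adjusted over the list alone (median -0.40, camera adjusted p = 0.0160, and adjusted p = 0.480 with an estimated correlation). The mean level of the list on serrated replicate 3, 6.46, lay above that of K-rasG12D replicate 1, 6.41. Etv5 fell by 2.55 ± 0.34 (adjusted p = 0.00456), Ier3 by 2.36 ± 0.34 (0.00619) and Dusp4 by 1.55 ± 0.29 (0.0192), and Emp1 rose by 1.69 ± 0.22 (0.00459). The list was not called without serrated replicate 1 (median -0.15, adjusted p = 0.210), with array weights (0.112), after quantile normalization (0.0550) or without the dimmest 40% of genes (0.191). Dusp4 did not pass without K-rasG12D replicate 1 or 2 or serrated replicate 2 (adjusted p of 0.0655 to 0.0903).

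Against K-rasG12D AOM tumors 1286 genes passed in limma, 490 higher and 796 lower in serrated tumors, and 982 differed by 2-fold or more. At an unadjusted p under 0.05 there were 4344. Of the 34 lists, 22 were called, 7 higher and 15 lower, only the Wnt list passed with an estimated correlation, and 10 passed in fry. The 12 other lists had adjusted p values from 0.0783 to 0.965. Without K-rasG12D replicates 1, 2 and 3, 501, 390 and 766 genes passed, without serrated replicates 2 and 3, 418 and 3186, and without serrated replicate 1, 1655, of which 59.5% were higher. Quantile normalization again gave 1949 genes with 48.3% higher, median centring 1074 with 52.4% higher, and array weights 9962, against 38.1% higher as deposited.

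Serrated tumors were then set against the LSL AOM tumors, which differed from them in every label. In serrated tumors 7 of 15 stomach genes and 5 of 18 small-intestinal genes rose, and 17 of 20 Wnt targets and 6 of 21 cell cycle genes fell. With an estimated correlation only the Wnt list was called (adjusted p = 0.0230, against 0.0941 to 0.368 for the others). Anxa10, an annexin of stomach epithelium, rose by 6.91 ± 1.29 on the log2 scale (adjusted p = 0.0204), Gkn2 by 6.80 ± 0.85 (0.00411), Gkn1 by 6.53 ± 0.77 (0.00351), Mucl3 by 6.46 ± 1.01 (0.0104) and Muc5ac by 6.32 ± 1.08 (0.0145). Spock2 fell by 5.82 ± 0.32, Prox1 by 5.4 ± 0.27 and Wif1 by 5.31 ± 0.28 (adjusted p = 0.000106 for each). Notum, a Wnt-inactivating enzyme, fell by 4.98 ± 0.28 (0.000106). The pancreatic lipase relative Pnliprp1 fell by 5.32 ± 0.71 (0.00534). Ctnnb1 fell by 0.83 ± 0.19 (0.0386) and Apc rose by 1.17 ± 0.26 (0.0335), while Cdkn2a (-0.21 ± 0.32, 0.75) and Vil1 (0.45, 0.346) did not pass. Leaving out LSL replicate 1 ended the calls of Anxa10, Gkn2, Mucl3 and Muc5ac, LSL replicate 2 those of Anxa10, Mucl3 and Muc5ac, and serrated replicate 2 that of Anxa10 (adjusted p of 0.0508 to 0.147). Ctnnb1 and Apc did not pass without any array but serrated replicates 1 and 3 (0.0519 to 0.262).

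Of the 20 Wnt targets, 17 fell, 0 rose and 3 did not pass, with 19 adjusted over the list alone (median -2.68, camera adjusted p = 2.14e-29, and adjusted p = 0.0230 with an estimated correlation). Nkd1 fell by 4.82 ± 0.24 (adjusted p = 0.000106) and Sox4 by 3.87 ± 0.22 (0.000106). Of 15 gastric genes, 7 rose, 0 fell and 8 did not pass, with 12 adjusted over the list alone (median 3.92, camera adjusted p = 3.25e-10, and adjusted p = 0.368 with an estimated correlation). Of 18 small-intestinal genes, 5 rose, 0 fell and 13 did not pass, with 9 rising and 1 falling when adjusted over the list alone (median 1.44, camera adjusted p = 6.98e-08, and adjusted p = 0.0941 with an estimated correlation). Rbp2 rose by 5.54 ± 0.41 (0.000393), Fabp2 by 5.48 ± 0.40 (0.000361), Apob by 4.36 ± 0.44 (0.00170) and Alpi by 3.84 ± 0.33 (0.000874). The small-intestinal median was 2.31 without the dimmest 40% of genes.

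Of 21 cell cycle genes, 6 fell, 0 rose and 15 did not pass, with 11 adjusted over the list alone (median -0.94, camera adjusted p = 5.95e-10, and adjusted p = 0.368 with an estimated correlation). Plk1 fell by 1.25 ± 0.25 (adjusted p = 0.0252), Top2a by 1.62 ± 0.36 (0.0341) and Mcm2 by 1.78 ± 0.40 (0.0353). Of 16 glycolysis and hypoxia genes, 5 rose, 1 fell and 10 did not pass, with 7 and 1 adjusted over the list alone (median 0.46, camera adjusted p = 0.00259, and adjusted p = 0.368 with an estimated correlation). Car9 rose by 1.70 ± 0.27 (0.0122), the glycolytic enzyme Pfkp by 1.05 ± 0.20 (0.0212) and Slc2a1 by 1.03 ± 0.18 (0.0171). None of these 6 genes passed without LSL replicate 1 or 2, nor Plk1, Top2a, Mcm2 and Slc2a1 without serrated replicate 2 (adjusted p up to 0.240). Plk1, Top2a and Mcm2 also failed without K-rasG12D replicate 1, Top2a and Mcm2 without K-rasG12D replicate 2 or 3, and Mcm2 without serrated replicate 1. The RAS/MAPK list was not called (median 0.10, adjusted p = 0.702). Of its 19 genes, Emp1 rose by 2.68 ± 0.25 (0.00124), and Etv5 (-1.95, 0.0219), Dusp4 (-1.67, 0.0235) and Ier3 (-1.73, 0.0344) fell, though not without serrated replicate 2 or either LSL array, nor Ier3 without any K-rasG12D array (adjusted p of 0.0514 to 0.245).

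Against LSL AOM tumors 1138 genes passed in limma, 460 higher and 678 lower in serrated tumors, and 929 differed by 2-fold or more. At an unadjusted p under 0.05 there were 4044. Of the 34 lists, 17 were called, 7 higher and 10 lower, only the Wnt list passed with an estimated correlation, and 7 passed in fry. The 17 other lists had adjusted p values from 0.119 to 0.896. Leaving out LSL replicate 1 or 2 gave 206 or 176 genes, K-rasG12D replicates 1, 2 and 3, 643, 759 and 754, serrated replicate 2, 391, replicate 3, 2530, and replicate 1, 1785 with 1062 higher. Quantile normalization again gave 1774 genes, array weights 6356 and a fit to only these 5 arrays 332. That last fit did not call Anxa10, Muc5ac, Ctnnb1, Apc, Etv5, Dusp4, Ier3, Plk1, Top2a, Mcm2, Slc2a1 or Pfkp (adjusted p of 0.0563 to 0.124). Ctnnb1 also did not pass after median centring (0.0562), nor Top2a with the mean of its probe sets (0.0695).

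The comparison of K-rasG12D with LSL AOM tumors held tumor type and colon segment fixed and asked what goes with the K-ras label. The titles of the LSL samples carry the abbreviation wt, and the labels do not say whether the LSL allele was silent in these tumors. No single gene passed. Of the 34 lists, 12 were called with the preset correlation, with RAS/MAPK, regenerative, hypoxia and neutrophil genes among those higher in K-rasG12D tumors and cell cycle and mast cell genes among those lower. None of the 12 was called with an estimated correlation (adjusted p = 0.626 to 0.684) or in fry, and the mast cell list was not called without LSL replicate 2 (median -0.13, adjusted p = 0.306). The genes of smallest p among the higher ones were the caspase Casp12, 5.68 ± 0.25 (SD, n = 3) against 3.66 ± 0.11 (SD, n = 2), and Cpe, a peptide-processing enzyme, 7.18 ± 0.70 (SD, n = 3) against 4.36 ± 0.19 (SD, n = 2). Their log2 differences were 2.02 ± 0.23 and 2.82 ± 0.38, beside 1.56 ± 0.20 for Ap1s3, 1.47 ± 0.20 for Tm4sf1 and 1.44 ± 0.20 for Faxc (adjusted p = 0.184 for each). Among the lower ones were Ccdc3 (-1.54 ± 0.22) and Pcyox1l (-1.43 ± 0.21, both 0.184), the Notch-modifying enzyme Lfng (-1.29, 0.222), the histone H4c6 (-1.82, 0.224) and Pex6 (-1.18, 0.224). Cdkn2a differed by 1.91 ± 0.32 (0.224), with all 3 K-rasG12D arrays above both LSL arrays, and did not pass. Ctnnb1 (-0.60, 0.40), Apc (0.83, 0.392) and Vil1 (-0.32, 0.871) did not pass either.

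Of 19 RAS/MAPK genes, 18 had positive differences, 0 passed over all genes and 4 passed when adjusted over the list alone (median 0.38, camera adjusted p = 4.01e-05, and adjusted p = 0.626 with an estimated correlation). Those 4 were the RAS pathway inhibitor Spred2 (1.02 ± 0.19), the transcription factors Etv4 (1.29 ± 0.24) and Egr1 (0.94 ± 0.28), and Emp1 (0.99 ± 0.25), with adjusted p over all genes of 0.239 to 0.384. Of 13 fetal and regenerative epithelium genes, 10 were positive and 4 passed over the list alone (median 0.41, camera adjusted p = 0.000303, and adjusted p = 0.626 with an estimated correlation). They were mesothelin Msln (2.01 ± 0.39), the cornified envelope gene Sprr1a (1.63 ± 0.36) and the annexins Anxa3 (0.91 ± 0.22) and Anxa1 (1.18). Of 16 glycolysis and hypoxia genes, 12 were positive and 4 passed over the list alone, the enzyme Pgk1 (1.04 ± 0.17), the peptide Adm (1.18 ± 0.21), Bnip3 (1.29) and Egln3 (1.48) (median 0.34, camera adjusted p = 0.000383, and adjusted p = 0.626 with an estimated correlation). The median of RAS/MAPK genes was 0.59 without LSL replicate 2, and that of regenerative genes 0.63 without K-rasG12D replicate 1.

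Lists of other cell types were also called with the preset correlation alone. Of 12 neutrophil genes, 11 were positive, and 3 higher and 1 lower passed over the list alone, the calprotectin genes S100a8 (1.97) and S100a9 (2.23), the chemokine receptor Cxcr2 (1.57) and Mmp9 (-1.21) (median 0.77, camera adjusted p = 0.000383, and adjusted p = 0.626 with an estimated correlation). The mean level of neutrophil genes overlapped between the groups, at 3.59 on K-rasG12D replicate 1 and 3.65 on LSL replicate 2. Of 12 endothelial genes, 9 were positive and 0 passed (median 0.35, camera adjusted p = 0.0156, and adjusted p = 0.651 with an estimated correlation). Of 13 mesenchymal genes, 11 were positive and 1, the transcription factor Twist1 (3.12 ± 0.71), passed over the list alone (median 0.38, camera adjusted p = 0.00221, and adjusted p = 0.626 with an estimated correlation). Of 11 mast cell genes, 9 were negative and the closely related proteases Mcpt2 (-2.81), Mcpt4 (-1.45) and Mcpt1 (-2.72) passed over the list alone (median -0.71, camera adjusted p = 0.000303, and adjusted p = 0.626 with an estimated correlation). All 21 cell cycle genes were negative with 0 passing (median -0.36, camera adjusted p = 0.000383, and adjusted p = 0.684 with an estimated correlation). Of 20 Wnt targets, 13 were negative, and 6 lower and 1 higher passed over the list alone (median -0.38, camera adjusted p = 0.00691, and adjusted p = 0.626 with an estimated correlation), led by Notum (-1.56 ± 0.28), Nkd1 (-1.18), Prox1 (-1.35) and Sox4 (-1.07). The mast cell list had a median of -1.41 without LSL replicate 1, and the neutrophil median was 0.49 without K-rasG12D replicate 2. The Wnt list was not called without K-rasG12D replicate 3 (median -0.20, adjusted p = 0.0605), nor the endothelial list without K-rasG12D replicate 2 (0.0997) or LSL replicate 2 (median 0.16, 0.429), and the mesenchymal median was 0.57 without K-rasG12D replicate 1.

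In limma 0 of 19938 genes passed between the AOM groups, with a smallest adjusted p of 0.184. At an unadjusted p under 0.05 there were 1666 genes, where 996.9 would be expected by chance. The spread behind these limma p-values is shared with the serrated arrays, which enter neither mean. A fit to only the 5 AOM arrays gave 3076 such genes. Leaving out serrated replicates 1, 2 and 3 in turn gave 2559, 1520 and 2227. The lack of calls therefore depends in part on the serrated arrays and does not show that the AOM groups are alike. Of the 12 lists called with the preset correlation, 8 were higher and 4 lower in K-rasG12D tumors. Those not described above were p53 targets (median 0.26, camera adjusted p = 0.0350), senescence-associated secretory factors (0.42, 0.0102) and oxidative phosphorylation (-0.23, 0.0139). They had adjusted p = 0.651 to 0.673 with an estimated correlation. The p53 list was not called without K-rasG12D replicate 1 (0.193) or 2 (0.0557) or LSL replicate 2 (0.336), the secretory list without K-rasG12D replicate 2 (0.0557) or LSL replicate 1 (0.124), and the oxidative list without K-rasG12D replicate 3 (0.0509) or LSL replicate 1 (0.124). The 22 other lists had adjusted p values from 0.0648 to 0.985. Array weights called 123 genes, and the fit to only these 5 arrays called 4, Serpinb11 (2.85), Irx5 (-1.69), Casp12 (2.02) and Alox15 (2.02), with adjusted p = 0.0442 for each. Without K-rasG12D replicate 1 there were 4, Twist1 (4.03, adjusted p = 0.00161), Smpx (-3.26, 0.0247), Cpe (3.22, 0.0247) and Slc38a4 (2.99, 0.0431), and without LSL replicate 1 there were 2, Mt4 (-3.82, 0.0282) and Krt35 (-3.53, 0.0436). All of these but Casp12 and Cpe were chosen after their values were seen.

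**Figure D3:**
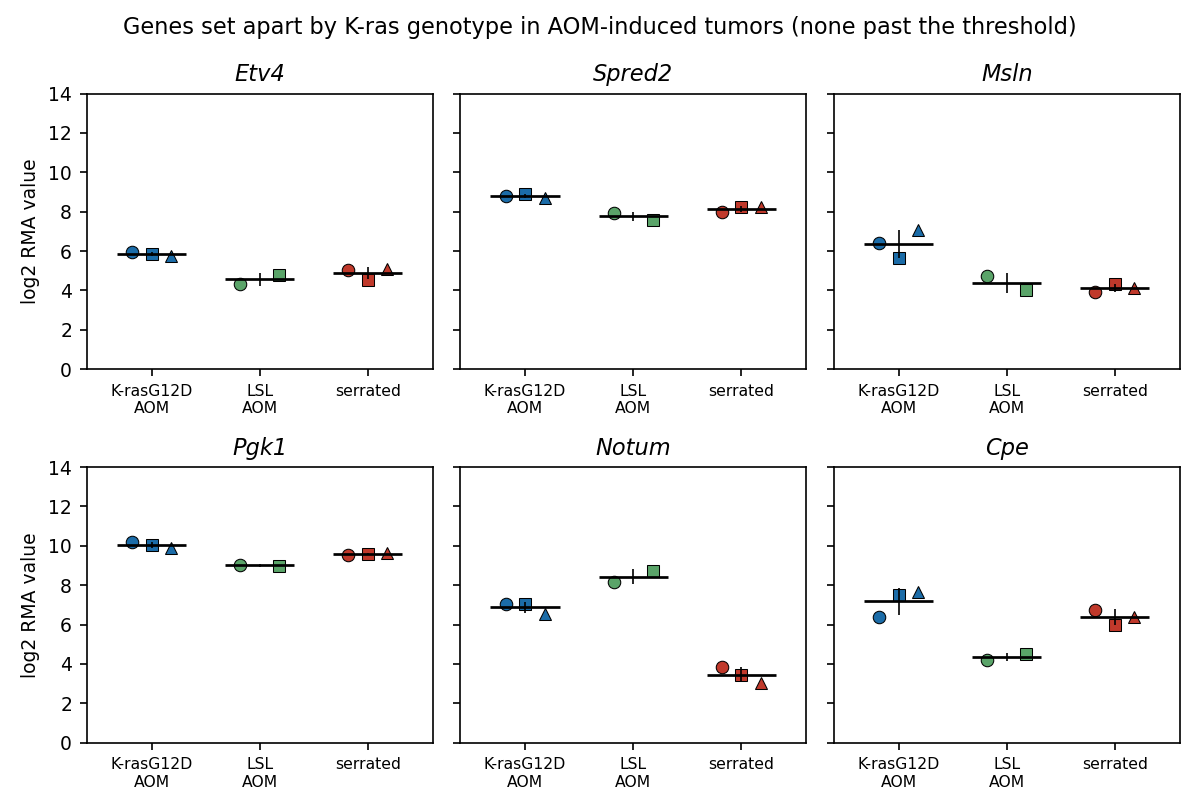
Log2 RMA values of Etv4, Spred2, Msln, Pgk1, Notum and Cpe on each of the 8 arrays, by group, with marker shape for the replicate, a line for the group mean and a bar for the SD. None of the 6 genes passed the threshold between the K-rasG12D and LSL AOM groups.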

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

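Array weights by the gene-by-gene method were chosen after the data were seen, and every other alternative before. Of the named genes, 60 of 100 kept their direction and side of the threshold under every alternative for serrated against all AOM tumors, 45 of 80 against K-rasG12D AOM tumors, 21 of 75 against LSL AOM tumors and 9 of 29 between the AOM groups. Between the AOM groups the other 20 were called under 1 or more alternatives, mostly array weights. Those called 19 of the genes by the default method and 18 by the gene-by-gene method, and a fit to only these groups called 1. Of the called lists, 12 of 17 for serrated against all AOM tumors, 14 of 22 against K-rasG12D AOM tumors, 10 of 17 against LSL AOM tumors and 6 of 12 between the AOM groups stayed called under every alternative run for lists that kept the set test. The robust option was not run for lists, because camera has no such option, and single probe sets were tested for genes only. With an estimated correlation and fry as well, 1 did in each serrated comparison and 0 between the AOM groups. From here on, counts of genes are given for serrated against all AOM, serrated against K-rasG12D AOM, K-rasG12D against LSL AOM and serrated against LSL AOM tumors, in that order. Array weights gave 10334, 9962, 123 and 6356 genes. The default method put a weight of 25.6 on serrated replicate 2, against 0.168 and 0.251 on serrated replicates 1 and 3, and did not converge, and the gene-by-gene method gave 5761, 5682, 58 and 3670 genes. Quantile normalization again gave 1949 for the second and 1774 for the last. A fit to only the groups compared gave 4 for the third and 332 for the last. Both had fewer arrays behind the spread, and the third no longer shared its spread with the serrated arrays. In the third, genes at an unadjusted p under 0.05 in limma went from 1666 to 3076, a rise that fewer arrays alone would not be expected to give. Leaving out each array in turn gave 643 to 3874, 390 to 3186, 0 to 4 and 176 to 2530 genes. Where that left 1 LSL array, it was assumed to vary like the other groups. Between serrated and LSL AOM tumors, Cdkn2a ran from -0.56 without LSL replicate 1 to 0.13 without LSL replicate 2, where its direction turned, and Top2a gave 0.0076 when every probe set was tested on its own. That value belongs to a second Top2a probe set with a mean level of 1.65, while the one used, with a mean of 7.18, stayed at -1.62. The cause of the other changes was not tested. Over all genes the median log2 difference after median centring was 0.10 for the first comparison and 0.14 for the second. Of called genes with several probe sets, 12 of 125, 3 of 68 and 11 of 81 had a probe set of opposite sign in the first, second and last comparison. No paired analysis was possible because the replicate numbers follow only the order of the samples. Signal over background was not measured, so differences among dim genes are less certain than those among bright ones.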

Other observations

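The tests of the compressed array and of non-epithelial cells were chosen after the results were seen, as was the second version of the test of neighbouring genes. The genes in this part were also chosen after their values were seen. The serrated tumors differed from each other in lineage genes. Serrated replicate 1 had the lowest mean level of stomach genes among the serrated arrays, and 3 apolipoproteins were highest there, Apoa4 at 9.99 against 5.07 and 4.08 on replicates 2 and 3, Apoa1 at 9.54 against 6.58 and 4.03, and Apoc3 at 5.68 against 3.26 and 2.87. Serrated replicate 2 had keratins of stratified epithelium, Krt5 at 8.73, Krt4 at 7.5 and Krt10 at 6.91. Krt5 also stood at 6.92 and 5.71 on K-rasG12D replicates 2 and 3 and at 5.10 on LSL replicate 2. Serrated replicate 3 had the collagenase Mmp13 at 8.85, against 4.24 and 4.23 on the other serrated arrays and 7.45 to 9.67 on the AOM arrays, and the stromelysin Mmp10 at 8.15, against 7.75 to 8.87 on the AOM arrays. Olfm4 stood at 4.03, 8.21 and 8.52 on the 3 serrated arrays.

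General epithelial genes did not pass between serrated and all AOM tumors in limma: Epcam differed by 0.05, Cdh1 by -0.01 and Krt8 by 0.32. Cdx2, a transcription factor of the intestine, rose by 2.56 ± 0.27 (adjusted p = 0.00130). Mtap, the measured gene next to Cdkn2a, fell by 1.95 ± 0.30 (0.00571). Focad, within 25 measured genes of Cdkn2a but not next to it, fell by 2.09 ± 0.29 (0.00413). Against LSL AOM tumors alone Mtap did not pass (-1.43, adjusted p = 0.0574).

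The splits were tested with a 2-group limma fit, which called 1655 genes between serrated and all AOM tumors where the fit of 3 groups called 1871, and 881 where it called 1286 against K-rasG12D AOM tumors. Between serrated and all AOM tumors, 1 of 56 splits of the 8 arrays into 3 and 5, the real one, gave as many genes. It gave 1655, against at most 1 in the other splits. That share is the smallest this test can give, so chance is made less likely but is not excluded. Every other split put serrated and AOM arrays together on the same side, which widens the spread. Low counts there do not show what no difference would give. Between serrated and K-rasG12D AOM tumors there are 10 splits, so the share cannot be under 0.1. The real split gave 881 genes, the highest other split 1, and 1 split, the real one, gave as many.

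Stomach genes were lower on serrated replicate 1 than on the other serrated arrays, 15 of 15 measured. A compressed range of that array could lower bright genes. For 13 gastric genes above a level of 6, the median residual from the array's own trend on level was -3.34, where 10000 random lists matched on level gave -0.261 to 0.267 in their central 95%. After quantile normalization the median deviation was -3.23, from -3.78 before. The test was chosen after the fall was seen. The random lists were drawn gene by gene, so their interval is too narrow for genes that move together and is not used here. The array's trend at the median level of these genes was -0.364, against their deviation of -3.78. That size argues against compression as the main cause. A difference between tumors, which the labels do not describe, stays open and untested.

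The macrophage and fibroblast lists were called lower in serrated tumors with the preset correlation but not with an estimated one. A lower share of all non-epithelial cells could give such a fall. Smooth muscle and endothelial genes with a mean level of 5 or more (13 genes) differed by -0.12 and macrophage and fibroblast genes (18 genes) by -1.14. The gap of 1.02 had a two-sided exact permutation p of 0.0179, the smallest that 56 splits can give, and was 0.85 without serrated replicate 1. Before this test was chosen, camera had called the macrophage and fibroblast lists, and not the smooth muscle and endothelial lists, on these same arrays. The gap and its p-value therefore restate that choice and cannot decide the question. An equal loss of all non-epithelial cells stays open, as does a change in macrophages and fibroblasts, or in the colon segment sampled. Cald1, a smooth muscle gene, fell in serrated tumors, unlike its list.

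A chromosome segment that came with the Ink4a/Arf allele could lower Mtap. Among the 25 measured genes on each side of Cdkn2a, 5 of 50 passed (10%), Focad, Ifna2, Mtap, Jun and Cyp2j6, against 9.39% of other genes. That count includes Mtap itself, the gene to be explained. The one-sided Fisher exact p was 0.511, with an odds ratio of 1.07 (95% interval 0.332 to 2.70). Without the dim genes 8 of 50 passed, with a one-sided Fisher exact p of 0.466. A segment and an effect of the deletion itself cannot be told apart for Mtap. Mtap also stood at 6.72, 7.18 and 6.70 in K-rasG12D AOM tumors and 5.83 and 5.85 in LSL AOM tumors, neither labelled Ink4a/Arf-/-. That log2 difference of 1.02 ± 0.37 did not pass in limma (adjusted p = 0.474). Part of the gap to K-rasG12D AOM tumors may therefore come without the allele. The interval is wide, and the genotype goes with tumor type, AOM and colon segment.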
